A study of Mus musculus with 9 samples.

How the data were processed

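Gene expression was measured with Affymetrix mouse gene arrays in cultured low-density bone marrow cells from Balb/c mice, the light fraction of marrow that holds blood cell progenitors. Per the labels' protocols, marrow was pooled, the cells were grown for 4 days with stem cell factor and FLT3 ligand at 100 ng/mL, and interleukin 5 (IL-5) followed. RNA was taken before IL-5 and after 4 and 10 days of IL-5, with 3 arrays at each time and 9 in all. Groups and replicate numbers came from the sample titles. Nothing in the labels says that the 3 arrays of a group were separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. A culture kept for the same days without IL-5 is not analysed here, so time in culture and IL-5 could not be separated in any comparison. Any change in stem cell factor and FLT3 ligand when IL-5 followed could not be separated from them either. The number of arrays limits the precision of every value.

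The deposited values were log2 signals per probe set on a common scale, with array medians from 5.67 to 5.75 and values from 1.63 to 14.5. Per the submitters' processing notes they were made with Affymetrix Expression Console 1.1.2637.26569, and the wording of the sample descriptions, per the labels, names its default gene-level RMA summary. The annotation release and the background and normalization settings of that step are not given in the sources used here. Robust multi-array averaging compresses changes of dim genes and forces similar distributions on all arrays, so a change shared by most genes would be understated. No detection calls were used. As a reference for dim genes, the lower quartile of the gene means over the 9 arrays was 4.66.

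Of 35557 probe sets, 21789 carried 1 gene symbol, 1621 named several genes and 12147 were unnamed in the probe table used here. Probe sets naming several genes or none were left out of the gene tests. Symbols were checked against current gene names through Entrez identifiers, which updated 0 symbols and left 91 as given. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 9 arrays was kept, which left 19938 genes. The array's genome build is not given in the sources used here, so no coordinates are printed, and the GRCm38.p6 gene table served only for names and for which genes are neighbours.

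Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 9 arrays, 3 group means, no covariate), with 6 residual and 6.47 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 19938 genes of each comparison. A gene was said to rise or fall when its adjusted p was under 0.05 and its change was at least 2-fold. Changes are differences of mean log2 signal, later minus earlier time. Tested on simulated arrays of 19938 genes, it found 99% of the genes planted with a log2 change of 1.5 at day 4, 99% at day 10 and 100% between the days, and 100% of those planted with a change of 3 in each comparison. Among unchanged genes it made 0, 0 and 2 false calls. In simulated and in deposited probe sets, the brightest probe set was kept for every gene checked (102 and 19938).

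A set of 33 gene lists, with 755 memberships of which 683 were measured, was fixed from textbook knowledge before the data were examined. The lists least covered by probe sets naming 1 gene were the eosinophil granule list, with 8 of 16 symbols standing for 7 genes, histone genes with 12 of 21 and erythroid markers with 10 of 15. Each list was tested in each comparison with limma's camera at a preset correlation of 0.01, adjusted over the 99 tests together. Camera with an estimated correlation was run beside it, and fry, which tests whether a list's genes move on balance in a shared direction. Camera compares a list with the other genes, so a list described as not shifted was not called by camera and may still be called by fry. Fry makes no such comparison, and 8440 of 19938 genes passed adjusted p alone at day 10 against the cells before IL-5. A call by fry alone therefore does not set a list apart from other genes. In a simulation with 1 shifted list, camera called that list and 0 of the other 32. Its genes were drawn independently of each other, so it does not cover lists whose genes vary together. Estimated correlations in the real lists reached 0.662, for interferon-stimulated genes. Camera p with the estimated correlation could also rise for a list whose estimate lay under 0.01. A call lost with that setting therefore need not come from genes varying together. Members past the gene test were counted, and counted again with p adjusted over the list alone. Time course classes were read from the 3 gene tests. Sustained genes changed in the same direction at both days against the cells before IL-5. Late genes passed at day 10 in the same direction against both earlier times and did not pass at day 4. They may have changed by less than 2-fold at day 4. Transient genes passed at day 4, passed in the opposite direction from day 4 to day 10, and did not pass at day 10 against the cells before IL-5. Their chance counts were taken from 100 simulations of unchanged groups that shared arrays as the real ones did.

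The genes named were set by a rule written before the data were examined. It took, per comparison, the 10 largest rises and the 10 largest falls among genes past the test whose arrays did not overlap, leaving out predicted models, antigen receptor segments, olfactory and vomeronasal receptors and small RNAs. It added up to 4 members of each list with the largest change past the test, or 2 members given as values where none passed, 17 genes always named, and the 6 largest transient and late genes in each direction. Genes named outside the rule complete a small count or a class, and were chosen after their values were seen. At day 4 they are Rnase2a, Hoxa9, Gfi1b, Il7r, Fcer1g, Mcpt8, Hsph1, Il12a, Mif, Cish, Pim1, Ccnd2 and Myc. At day 10 they are Rnase2a, Id1, Myc, Spry2, Il12a, Mif, Ccl5, Cxcr2, Chil3, Ccr2, F13a1, Cx3cr1, Tcf4, Ciita, Siglech, Osm, Fcer1a, Cma1, Eomes, Hk2, Hk3, Ptges3, Ptger3, Ctsb, Ctsl, Ctsz, Gbp3, Itga6, Bcl2l1, H2-Eb1 and H2ax. Between the days they are Pim2, Socs1, Egr1, Ly6g, Adgre1, Cd79a, Hk2, Pfkfb3, Pparg, Hpgds, Itgb7 and the plotted Ifit3. Further genes that only the closing section names were also chosen after their values were seen. Of 240 named genes, 9 had more than 1 probe set and 3 of these were called by the kept probe set but not by every other.

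Alternatives were quantile normalization or subtraction of array medians, leaving out dim genes, averaging probe sets, testing every probe set, other variance priors, array weights, fits to 6 arrays, replicate numbers as blocks, other thresholds, camera on ranks, and leaving out each array in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.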

Results

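Low-density bone marrow cells of Balb/c mice were expanded with stem cell factor and FLT3 ligand and then given IL-5, the cytokine that drives the formation of eosinophils. Expression was profiled before IL-5, at day 4 and at day 10 of IL-5, in 3 arrays each, to ask which genes change as the cultures turn towards eosinophils. Values are log2 signals, and means carry the SD of 3 arrays. Arrays of a group were closer to each other than to any other group, with correlations across genes of 0.991 to 0.996 within groups and 0.927 to 0.936 between the cells before IL-5 and those at day 10. The leading principal component held 64.6% of the variance and ordered the arrays from before IL-5 through day 4 to day 10. The next held 21.9% and set the day 4 arrays apart from both others.

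By day 4 the eosinophil granule genes Epx, Prg2, Prg3 and Ear6 stood higher than before IL-5, and red cell genes such as Car1 and Rhag stood lower. The mRNA of eosinophil peroxidase, Epx, rose from 8.29 ± 0.118 to 12.84 ± 0.081 (SD, n = 3), a 23.4-fold change with an adjusted p of 6.9e-11. Prg2, which encodes major basic protein, was already at 10.72 ± 0.229 before IL-5 and rose to 13.42 ± 0.044. The eosinophil ribonuclease Ear6 rose by 4.64, the major basic protein homologue Prg3 by 4.01 and the lipoxygenase Alox15 by 3.99. The largest falls were in red cell genes, led by carbonic anhydrase Car1 with a log2 change of -4.80 (adjusted p = 6.79e-10), followed by Cldn13 (-3.41), the Rh-associated glycoprotein Rhag (-3.40), the water channel Aqp1 (-3.08) and Ermap (-3.02). Ear6 and the cystatin gene Stfa3, which rose by 4.62, belong to families of near-identical copies that an array can mix, so their identity is uncertain. Dab2 rose by 4.14 on the probe set used, while its other probe set gave 0.08. The remaining genes among the largest rises were C3ar1, Cd36, Lipg and C1qc, each by 3.99 or more. In all, 1102 of 19938 genes passed at day 4, of which 682 rose and 420 fell, and in all 1102 the arrays before IL-5 and at day 4 did not overlap. Non-overlap held for 43.6% of all genes against 10% expected by chance.

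**Figure D1:**
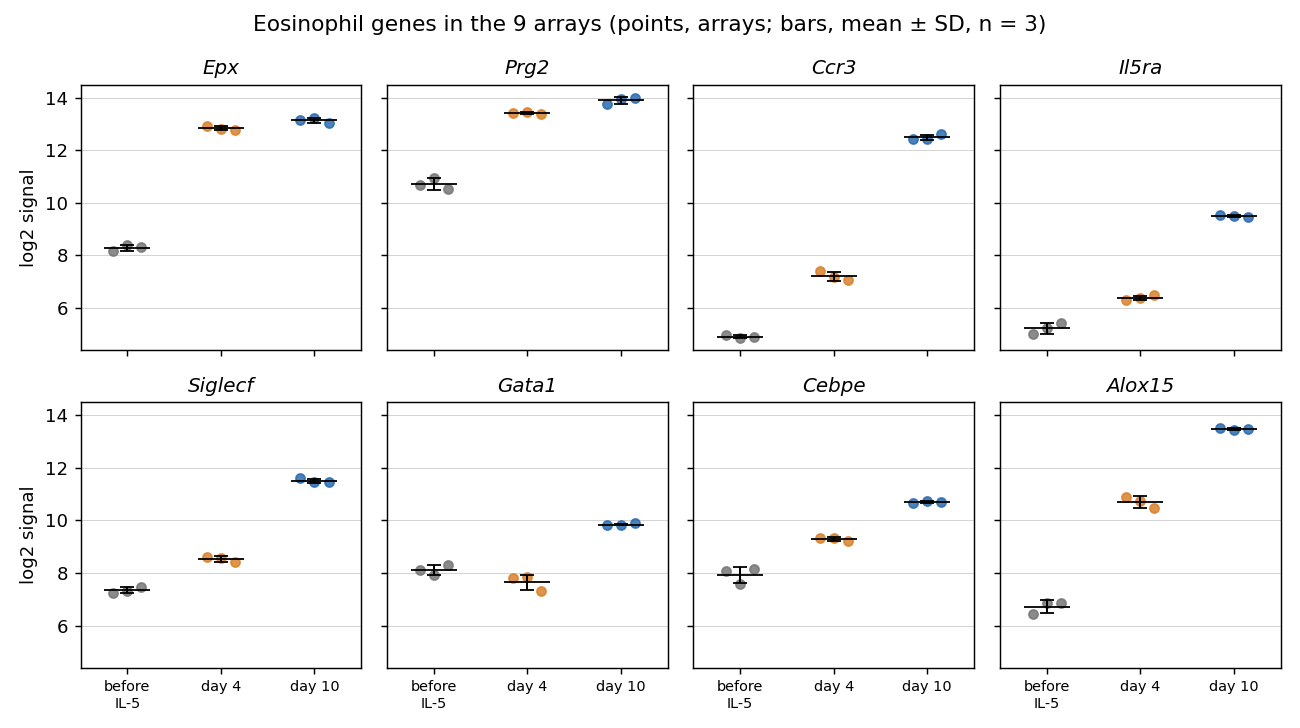
Log2 signal of 8 eosinophil genes in each of the 9 arrays (points) before IL-5, at day 4 and at day 10, with the mean and SD of 3 arrays (bars). Epx and Prg2 reach 12.84 and 13.42 by day 4, while Ccr3 stands at 7.21 at day 4 and 12.49 at day 10, and Gata1 rises only after day 4.

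Among eosinophil surface receptors, 10 of 15 measured genes rose at day 4 and 0 fell (camera adjusted p = 3.58e-11, and 0.0172 with an estimated correlation). The complement receptor C3ar1 rose by 4.40, the eotaxin receptor Ccr3 by 2.30, P2ry14 by 1.94, Pirb by 1.85, Siglecf by 1.19 and the IL-5 receptor chain Il5ra by 1.16. Of the 7 granule list genes measured, which leave out most Ear ribonucleases, 4 rose and Rnase2a fell, with a log2 change of -1.12 (camera adjusted p = 1.57e-05; adjusted p = 0.0697 with an estimated correlation). Without day 4 replicate 3, Rnase2a stood at -0.99 and 0 granule genes fell. Among 12 lineage transcription factors only Trib1 (1.38) and Cebpe (1.35), a C/EBP factor of late granulocyte maturation, rose (camera adjusted p = 0.00867; adjusted p = 0.202 with an estimated correlation). Gata1 (-0.47), Gata2 (-0.50), Cebpa (-0.25), Spi1 (0.67), Id2 (0.67) and Xbp1 (0.68) did not reach a 2-fold change.

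Stem and progenitor genes went down, with 6 of 18 falling and 0 rising (camera adjusted p = 0.000198, and 0.0343 with an estimated correlation). They were Cd34 (-2.29), Sox4 (-1.40), Meis1 (-1.27), Mycn (-1.22), Hoxa9 (-1.12) and Gfi1b (-1.11), whereas the growth factor receptors Kit (-0.26) and Flt3 (-0.09) did not pass. Erythroid markers fell in 7 of 10 genes (camera adjusted p = 4.59e-09, and 0.0178 with an estimated correlation), Car2 by -2.99 among them. B cell markers fell in 8 of 14, including the pre-B gene Vpreb3 (-2.92), the recombinase Rag1 (-2.82), Ebf1 (-2.65) and Cd79a (-2.64), while Il7r rose by 1.01 (camera adjusted p = 1.69e-07, and 0.0262 with an estimated correlation). Il7r lay at the 2-fold limit, and stood at 0.99 without replicate 1 and at 0.97 without replicate 3 before IL-5. Genes of T and NK cells, megakaryocytes, mast cells and neutrophil primary granules were not shifted as lists at day 4, with camera adjusted p of 0.248, 0.847, 0.274 and 0.477. Of these lists, fry called only that of T and NK cells (adjusted p = 0.000899). Gzma (-1.49), Eomes (-1.21) and Gzmb (-1.27) fell within these lists, and Treml1 (-0.38), Rab27b (-0.32), Ctsg (-0.92) and Cst7 (-0.44) did not pass.

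Neutrophil later granule and maturation genes rose at day 4 in 17 of 20, among them Ly6g (2.62), Chil1 (2.51), Chil3 (2.45) and lactoferrin, Ltf (2.27), with camera adjusted p = 6.88e-21 and adjusted p = 0.0505 with an estimated correlation. Monocyte and macrophage markers rose in 14 of 21, led by the complement genes C1qc (3.99) and C1qb (3.66), the mannose receptor Mrc1 (3.69) and Fcgr1 (3.08), with camera adjusted p = 2.65e-14 and adjusted p = 0.129 with an estimated correlation. Dendritic cell markers rose in 10 of 18, including the chemokine Ccl22 (3.28), the homing receptor Ccr7 (3.18), Cd83 (2.37) and Siglech (2.13), with camera adjusted p = 8.3e-12 and 0.0243 with an estimated correlation. Antigen presentation genes rose in 8 of 17, with Cd86 (2.03), Cd74 (1.74), Ctss (1.70) and Cd80 (1.68), and camera adjusted p = 1.12e-12, or 0.0343 with an estimated correlation. Basophil markers rose in 5 of 15, Ccl3 (2.11), Cyp11a1 (1.70), Ccl4 (1.41), Osm (1.37) and Fcer1g (1.04), and Mcpt8 fell (-1.20; camera adjusted p = 0.00975; adjusted p = 0.268 with an estimated correlation). Fcer1g stood at 0.96 without replicate 3 before IL-5, and 2 basophil markers fell without replicate 1 or 3 before IL-5 or without day 4 replicate 1 or 2. Of 16 stromal and endothelial markers only the VEGF receptor Kdr rose (2.62), against 3 without day 4 replicate 1. The camera adjusted p of that list was 0.0232, or 0.0528 without day 4 replicate 3, and adjusted p = 0.209 with an estimated correlation, in a range from 0.00753 to 0.209 over all alternatives.

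Interferon-stimulated genes rose at day 4 in 23 of 26, for example Ifit3 (3.10), Oasl2 (2.97), the transcription factor Irf7 (2.62) and Rsad2 (2.53), with camera adjusted p = 1.47e-29 and adjusted p = 0.0697 with an estimated correlation. Immediate early and stress genes rose in 14 of 25, led by the phosphatase gene Dusp1 (3.31), Fos (3.30), Atf3 (2.37) and Zfp36 (1.83), and Hsph1 fell (-1.16), with camera adjusted p = 1.11e-13, or 0.0343 with an estimated correlation. Cytokines and chemokines rose in 15 of 52, with Il1b at 3.52, Il12b at 3.36 and Cxcl16 at 3.26, while Il12a (-1.63) and Mif (-1.05) fell (camera adjusted p = 1.3e-09; adjusted p = 0.0735 with an estimated correlation). Mif missed the 2-fold limit without day 4 replicate 3, which left 1 fall, and Il4 stood 0.53 higher without passing. Among their receptors 9 of 33 rose, with Ccr1 at 1.75, Ccrl2 at 1.49 and Il10ra at 1.43 (camera adjusted p = 1.15e-09; adjusted p = 0.111 with an estimated correlation). Of the IL-5 and STAT5 targets, Socs2 (3.34), Dusp5 (1.81), Egr1 (1.62), Osm (1.37), Cish (1.23) and Pim1 (1.16) rose, and Bcl2 (-2.06), Ccnd2 (-1.26) and Myc (-1.24) fell (camera adjusted p = 0.00347, and adjusted p = 0.197 with an estimated correlation). The other probe set of Socs2 gave 1.29, so its place ahead of Dusp5 rests on the probe set used.

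Ribosome biogenesis genes fell at day 4 in 17 of 29, such as the pseudouridine synthase Dkc1 (-1.51), the polymerase I subunit Polr1b (-1.42), Wdr12 (-1.36) and Nat10 (-1.36), and camera adjusted p was 7.09e-18, or 0.0343 with an estimated correlation. DNA replication genes fell in 14 of 33, including Gins1 (-1.43), Mcm7 (-1.24), Rfc3 (-1.15) and Mcm2 (-1.12), with camera adjusted p = 1.06e-16 and 0.0343 with an estimated correlation; after quantile normalization 9 fell. Mitosis genes had a median change of -0.64 with only Nek2 (-1.28) past the test (camera adjusted p = 2.53e-10; adjusted p = 0.0837 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.53 with 0 of 35 past the test, the largest values being Ndufa9 (-0.89) and Ndufv1 (-0.86), with camera adjusted p = 1.21e-09 and adjusted p = 0.129 with an estimated correlation. Lysosome genes rose in 9 of 27, led by the cathepsins Ctsb (1.98), Ctsh (1.77), Ctss (1.70) and Ctsl (1.68), with camera adjusted p = 1.5e-15 and adjusted p = 0.054 with an estimated correlation. Eicosanoid genes rose in 7 of 24, with the cyclooxygenase Ptgs2 at 2.23, Pla2g7 at 2.06 and Pparg at 1.54 besides Alox15, and camera adjusted p = 1.91e-08, or 0.0368 with an estimated correlation. Integrins Itgam (1.82) and Itgb2 (1.32) were the 2 of 22 adhesion genes that rose (camera adjusted p = 8.23e-07; adjusted p = 0.0505 with an estimated correlation). Cholesterol synthesis genes shifted up by a median of 0.26 with 0 of 19 past the test, Cyp51 at 0.67 and Msmo1 at 0.66 (camera adjusted p = 0.000103; adjusted p = 0.12 with an estimated correlation). Apoptosis regulators Pmaip1 (1.37) and Birc3 (1.16) rose and Bcl2 and Bid fell (camera adjusted p = 0.00242; adjusted p = 0.242 with an estimated correlation). Bid lay at the 2-fold limit, and stood at -0.96 without replicate 1 or 3 before IL-5, at -0.91 without day 4 replicate 3 and at -0.98 after quantile normalization or subtraction of array medians. Without day 4 replicate 2, or after quantile normalization, 4 apoptosis regulators rose.

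The unfolded protein response list had 0 of 24 genes past the test at day 4, with Asns at -0.86. Camera nevertheless called the list as shifted up (adjusted p = 0.0369), with a median change of 0.04. That call was lost without replicate 3 before IL-5 (0.0953), without day 4 replicate 1 (0.0856) or 3 (0.0579), and adjusted p = 0.297 with an estimated correlation, in a range from 0.0127 to 0.297 over all alternatives. The glycolysis list was not called (camera adjusted p = 0.0639, and 0.0305 without replicate 1 before IL-5 or 0.0454 without day 4 replicate 2, in a range from 0.0305 to 0.537), although Pfkfb3 (1.66), Slc2a3 (1.32), Slc16a3 (1.15) and Aldoc (1.12) rose. Histone genes were not shifted (camera adjusted p = 0.23), with H1f2 at 1.09 and H2ac4 at -1.06 past the test, and H2ac4 at -0.98 without replicate 3 before IL-5. At day 4, 27 of 33 lists were shifted, 20 up and 7 down, and 10 calls held with an estimated correlation. Fry also called the histone (adjusted p = 0.00749) and glycolysis lists (adjusted p = 0.0195), which camera did not. Counts adjusted over the list alone equalled those over all genes for the 33 lists.

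At day 10 against the cells before IL-5 the eosinophil surface receptor genes Ccr3, C3ar1, Il5ra and Siglecf stood far higher. Ccr3, the receptor for eotaxins, showed the largest change of any named gene, from 4.91 ± 0.063 to 12.49 ± 0.107 (SD, n = 3), a 191-fold rise in signal with an adjusted p of 3.56e-13. The starting level lay close to that of dim genes, where changes are compressed and no detection call was used, so the size of this fold is uncertain. The serpin gene Serpinb2 rose by 6.93, Alox15 by 6.78, the inositol phosphatase Inpp5j by 5.89, the cystine transporter Slc7a11 by 5.79, the lipase Lipg by 5.61, the cytochrome Cyp4f18 by 5.50, Ear6 by 5.47, the chemokine Ccl6 by 5.02 and the deiminase Padi4 by 4.99. The neutrophil granule protease cathepsin G, Ctsg, fell the most among the named genes, with a log2 change of -5.49, and elastase, Elane, had -3.93. Car1 (-4.97), Cd79a (-4.05), the melanocortin receptor Mc5r (-3.89), B3gnt5 (-3.86), myeloperoxidase, Mpo (-3.78), Car2 (-3.70), Adgrl4 (-3.65) and Cd79b (-3.64) fell too. In this comparison 2839 genes passed, 964 rising and 1875 falling, so that 66.0% of the changes were falls, and in 2837 of them the arrays did not overlap. After quantile normalization 57.8% were falls. Non-overlap held for 49.7% of all genes against 10% by chance.

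Of the eosinophil surface receptors 11 of 15 rose by day 10, with Ccr3 followed by C3ar1 (4.97), Il5ra (4.27) and Siglecf (4.17), and camera adjusted p = 1.49e-11, or 0.0172 with an estimated correlation. The granule genes Ear6, Epx (4.85), Prg3 (4.68) and Prg2 (3.18) rose and Rnase2a fell (-1.67), with camera adjusted p = 0.00018 and adjusted p = 0.0975 with an estimated correlation. Among lineage factors Cebpe (2.77), Trib1 (2.59), Gata1 (1.73), Id2 (1.70) and Id1 (1.47) rose, and Irf8 (-2.20) and Cebpa (-1.30) fell (camera adjusted p = 0.00333; adjusted p = 0.161 with an estimated correlation). Gata2 (0.18), Spi1 (0.99) and Xbp1 (0.29) did not pass, but Spi1 passed at 1.03 without day 10 replicate 1, at 1.05 without day 10 replicate 3 and at 1.08 after quantile normalization, and also without replicate 2 before IL-5. IL-5 and STAT5 targets rose in 10 of 19, led by the feedback inhibitors Socs2 (4.90) and Cish (3.98). The other probe set of Socs2 gave 2.31, so its lead over Cish rests on the probe set used. The cyclins Ccnd2 (-2.98) and Ccnd1 (-2.75), Myc (-2.22), Bcl2 (-1.61) and Spry2 (-1.39) fell (list camera adjusted p = 0.000251, and adjusted p = 0.12 with an estimated correlation). Cytokines and chemokines rose in 11 of 52, with Csf1 at 4.48, Il1rn at 3.58, Il1a at 3.29, Ccl3 at 2.51 and Il4 at 2.02 besides Ccl6, and Il12a (-2.73), Mif (-1.29) and Ccl5 (-1.05) fell (camera adjusted p = 0.000198; adjusted p = 0.204 with an estimated correlation). Without day 10 replicate 1, Ccl5 stood at -0.99. Their receptors were not shifted (camera adjusted p = 0.486), with 6 rising, Ccr1 by 3.23, and 8 falling.

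Progenitor genes fell in 10 of 18 by day 10, including Cd34 (-3.62), Flt3 (-3.55), Sox4 (-2.81) and Kit (-2.54), with camera adjusted p = 0.000411 and 0.0368 with an estimated correlation. B cell markers fell in 12 of 14, Rag1 (-3.44) and Ebf1 (-3.39) among them (camera adjusted p = 1.38e-08, and 0.0235 with an estimated correlation). Erythroid markers fell in 8 of 10, such as Car2 and Rhag (-3.32), and Gata1 was the member that rose (camera adjusted p = 6.67e-05, and 0.0343 with an estimated correlation). Primary granule genes fell in 7 of 10, with the proteinase Prtn3 at -3.59 (camera adjusted p = 0.000208; adjusted p = 0.204 with an estimated correlation). Of 20 later neutrophil genes, Ly6g (3.77), Mmp9 (2.33), Retnlg (2.27), Cybb (1.67) and Cxcr2 (1.48) rose and Chil3 fell (camera adjusted p = 0.000374; adjusted p = 0.319 with an estimated correlation). Chil3 stood at -0.68 without day 10 replicate 1 and at -0.94 without replicate 1 before IL-5, so that 0 of the list then fell. Monocyte and macrophage markers rose in 9 of 21, led by Adgre1 (4.24), Mrc1 (3.63), C1qc (3.40) and Gpnmb (2.74), and Ccr2 (-1.82), F13a1 (-1.78) and Cx3cr1 (-1.55) fell (camera adjusted p = 0.000836; adjusted p = 0.437 with an estimated correlation).

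The 3 day 10 arrays differed in these myeloid genes. Mrc1 was 8.08, 7.43 and 9.86 in day 10 replicates 1, 2 and 3, Mpo was 8.17, 8.83 and 9.79, and F13a1 was 8.51, 8.72 and 10.54, with replicate 3 the highest in each. Leaving replicate 3 out raised the genes passing at day 10 to 3004. Dendritic cell markers fell in 6 of 18, Flt3, Irf4 (-2.59), Cd209a (-1.76), Tcf4 (-1.72), Ciita (-1.43) and Siglech (-1.15), and Cd80 rose by 1.78 (camera adjusted p = 0.00756; adjusted p = 0.164 with an estimated correlation). Basophil markers split, with Cyp11a1 (3.34), Ccl3, Il4, Osm (1.85) and Itga2b (1.30) up and Cd69 (-2.45), Mcpt8 (-2.11) and Fcer1a (-1.67) down (camera adjusted p = 0.0284; adjusted p = 0.329 with an estimated correlation). Acta2 (1.13) and Col1a2 (1.03) were the stromal markers that rose (camera adjusted p = 0.024; adjusted p = 0.21 with an estimated correlation), and without day 10 replicate 3 they stood at 0.83 and 0.50, below the 2-fold limit, with array weights at 0.96 and 0.83. Col1a2 also missed the test without replicate 1, 2 or 3 before IL-5, with adjusted p of 0.0866, 0.0591 and 0.0783, in a range from 0.00381 to 0.547 over all alternatives. Mast cell markers Kit, Cpa3 (-2.44), Gzmb (-2.00), Mcpt2 (-1.49) and Cma1 (-1.23) fell. Camera did not call their list (adjusted p = 0.083), but fry did (adjusted p = 9.39e-06). Megakaryocyte markers were not shifted (camera adjusted p = 0.87), with F2r (2.46) and Itga2b up and Rab27b (-1.04) down. Rab27b stood at -0.95 without replicate 3 before IL-5 and at -0.93 without day 10 replicate 1, so that 0 of these markers then fell. T and NK cell markers were not shifted (camera adjusted p = 0.563), yet Cd3g rose by 3.21 and Cd3d by 1.49, while Klrd1 (-1.43), Gzma (-1.32) and Eomes (-1.16) fell, Eomes standing at -0.98 without day 10 replicate 1.

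Ribosome biogenesis genes fell at day 10 in 29 of 29, with Dkc1 at -2.52, Gnl3 at -2.34, Tsr1 at -2.32 and Polr1b at -2.25 (camera adjusted p = 3.05e-17, and 0.0343 with an estimated correlation). All 29 also fell after quantile normalization. DNA replication genes fell in 31 of 33, Gins1 (-2.53), Prim1 (-2.23), Mcm2 (-2.22) and Mcm6 (-2.08) the most, and camera adjusted p was 7.09e-18, or 0.0343 with an estimated correlation. Mitosis genes fell in 18 of 29, including Nek2 (-1.86), Bub1 (-1.71), Bub1b (-1.69) and Aurkb (-1.48), with camera adjusted p = 1.12e-12 and adjusted p = 0.0601 with an estimated correlation. Oxidative phosphorylation genes fell in 13 of 35, such as Ndufa9 (-1.48), Cycs (-1.43), Cyc1 (-1.39) and Ndufab1 (-1.36), with 8 after quantile normalization (camera adjusted p = 1.88e-10; adjusted p = 0.12 with an estimated correlation). Of the glycolysis list, the lactate exporter Slc16a3 (3.20), the glucose carriers Slc2a3 (3.09) and Slc2a1 (1.79), Aldoc (1.76) and Hk2 (1.23) rose and Hk3 fell (-1.59; camera adjusted p = 0.00153; adjusted p = 0.298 with an estimated correlation). Eicosanoid genes rose in 7 of 24, with Pla2g7 at 3.67, the 5-lipoxygenase gene Alox5 at 2.98 and the leukotriene receptor Ltb4r1 at 2.29 after Alox15, and Ptges3 (-1.33) and Ptger3 (-1.03) fell (camera adjusted p = 0.00308; adjusted p = 0.161 with an estimated correlation). Ptger3 stood at -0.98 without replicate 3 before IL-5, and at -0.99 and -0.89 without day 10 replicate 1 or 2.

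Lysosome genes rose in 6 of 27 at day 10, with Ctsh (2.72), Cd63 (2.11), Ctsd (1.89) and Neu1 (1.86) the highest (camera adjusted p = 1.66e-05; adjusted p = 0.209 with an estimated correlation). When day 10 replicate 3 was left out, 4 rose, with Ctsb at 0.95 and Ctsl at 0.81, and Ctsz fell (-1.09). Interferon-stimulated genes still stood higher in 13 of 26, Oas2 (2.02), Rsad2 (1.99), Oas3 (1.83) and Ifit3 (1.77) the most, and Gbp3 fell by 1.05 (camera adjusted p = 1.14e-08; adjusted p = 0.263 with an estimated correlation). Gbp3 stood at -0.97 without replicate 3 before IL-5, and at -0.90 and -0.83 without day 10 replicate 1 or 2. Immediate early and stress genes rose in 6 of 25, with Dusp1 at 3.47, Gadd45a at 2.76 and Klf6 at 1.90, and Hsph1 fell by 1.74 (camera adjusted p = 0.000141; adjusted p = 0.129 with an estimated correlation). Adhesion genes rose in 6 of 22, including Itgam (2.29), Itgb2 (2.04) and Itgb7 (1.46), and Itga1 (-2.49) and Itga6 (-1.01) fell (camera adjusted p = 0.00864; adjusted p = 0.204 with an estimated correlation). Itga6 stood at -0.86 without replicate 2 before IL-5, and at -0.91 and -0.80 without day 10 replicate 1 or 2. Apoptosis regulators Mcl1 (1.34), Birc3 (1.29), Fas (1.17) and Bcl2l1 (1.04) rose and Bcl2 (-1.61) fell (camera adjusted p = 0.0279; adjusted p = 0.372 with an estimated correlation). Bcl2l1 stood at 0.97 without replicate 1 before IL-5 and at 0.99 without day 10 replicate 3. Antigen presentation genes were not shifted as a list by camera (adjusted p = 0.198), but fry called them (adjusted p = 0.000213). H2-DMa (-1.68), H2-Ab1 (-1.56), H2-Aa (-1.46), Ciita and H2-Eb1 (-1.24) fell, and 1 member rose. Cholesterol synthesis, with Insig1 at -1.06 and below the 2-fold limit without day 10 replicate 2 (0 then fell) or after quantile normalization (-0.97), and the unfolded protein response, with Asns at -1.29, were not shifted (camera adjusted p = 0.203 and 0.332). Histone genes were not shifted (camera adjusted p = 0.0988, and 0.0415 without day 10 replicate 2, in a range from 0.0415 to 0.452), with H1f2 (1.98) and H2bc4 up and H2ac4 (-1.43), H1f1 (-1.12) and H2ax (-1.03) down. Without day 10 replicate 2, 6 histone genes fell, H2ax stood at -0.94 without replicate 2 before IL-5 and missed the limit without day 10 replicate 1, and H1f1 did so after quantile normalization, where 1 histone gene fell. At day 10, 25 of 33 lists were shifted, 16 up and 9 down, and 6 calls held with an estimated correlation. Of the lists camera did not call, fry also called histone (adjusted p = 0.000866), cholesterol synthesis (adjusted p = 0.0011) and T and NK cell genes (adjusted p = 0.00556). Counts adjusted over the list alone were again the same.

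**Figure D2:**
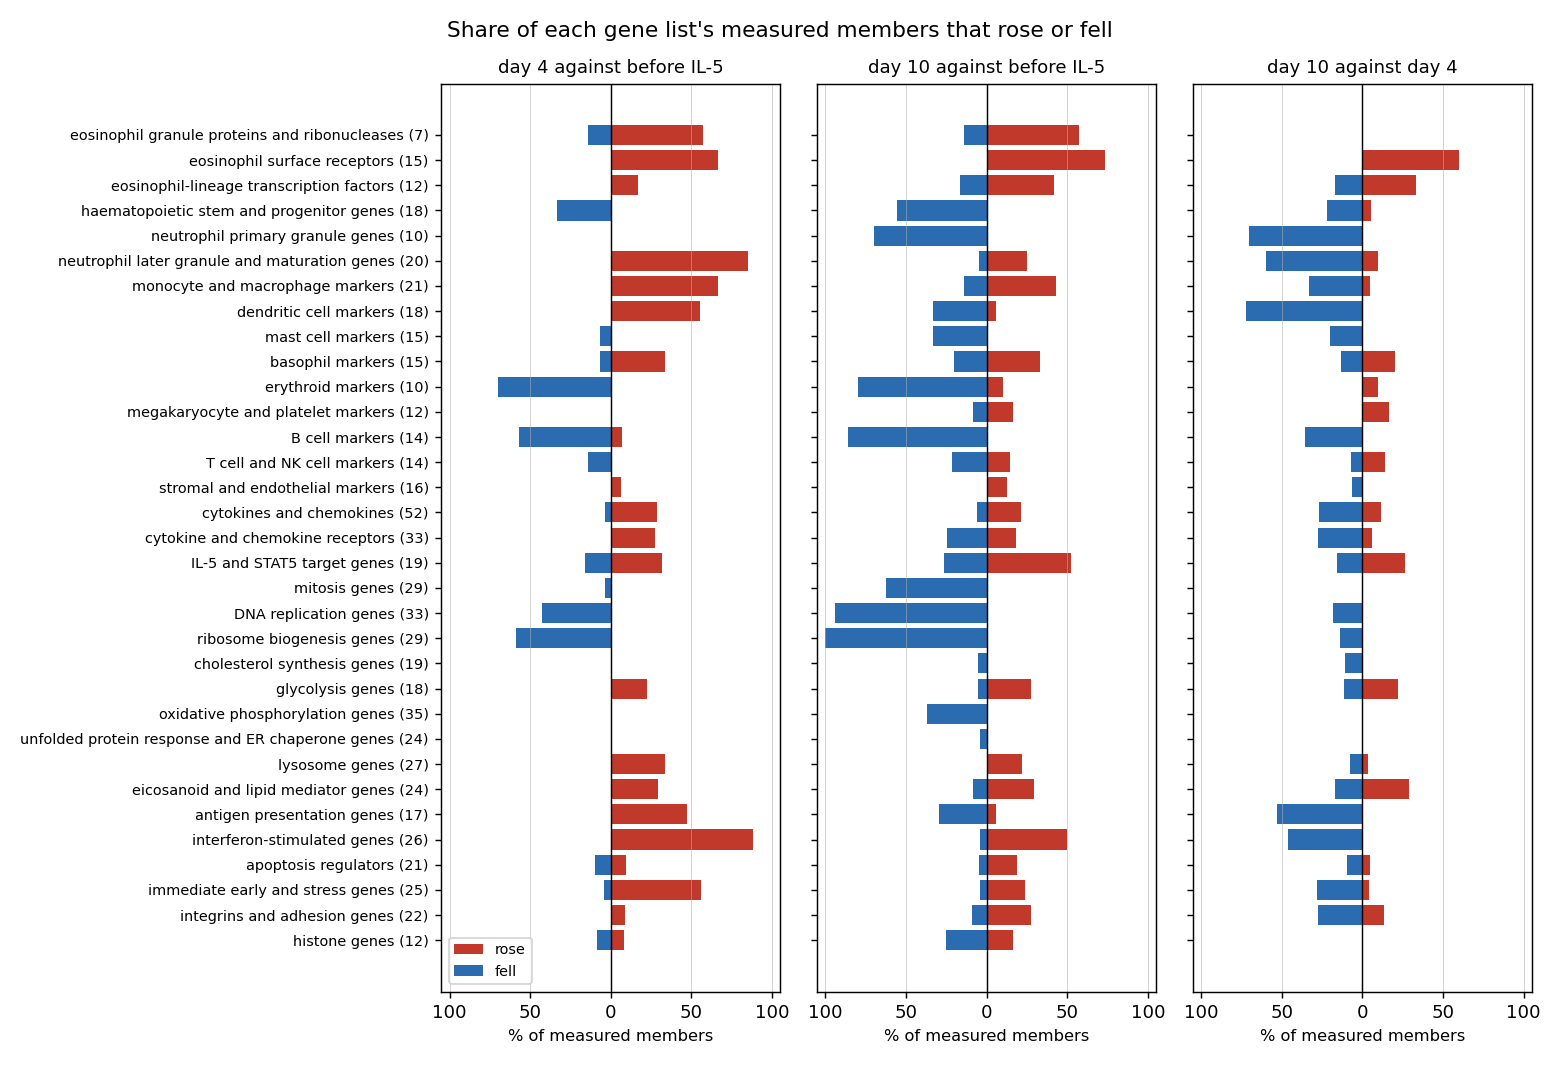
Percent of each gene list's measured members (number in brackets) that rose (red, right) or fell (blue, left) in the 3 comparisons. Ribosome biogenesis reaches 29 of 29 falling at day 10, interferon-stimulated genes 23 of 26 rising at day 4, and dendritic cell markers 13 of 18 falling from day 4 to day 10.

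From day 4 to day 10 the eosinophil receptor genes Ccr3, Il5ra and Siglecf rose further. Ccr3 rose by 5.28 (adjusted p = 3.19e-11), Il5ra by 3.11, Siglecf by 2.98 and the prostaglandin receptor Ptgdr2 passed too, and Gata1 went from 7.65 ± 0.29 to 9.85 ± 0.038 (SD, n = 3). Epx (0.31), Prg2 (0.49), Prg3 (0.67) and Ear6 (0.82) stood higher by less than 2-fold. Epx and Prg2 were already high at day 4, when the highest value of any probe set was 14.5. The size of their further rise is therefore uncertain. Besides Ccr3 the largest rises were Cyp4f18 (4.59), Tmem71 (4.15), Inpp5j (4.12), the water channel Aqp9 (3.92), the monocarboxylate carrier family gene Slc16a9 (3.80), the actin regulator Enah (3.76), Cd3g (3.74), Bank1 (3.71) and Ccn3 (3.69). At day 4 Cd3g lay below the lower quartile of gene means of 4.66, so the size of its rise is uncertain. For Slc16a9, whose other probe set gave 0.24, the rise rests on the probe set used. Ctsg (-4.57), Ccr7 (-4.12), the peptidase Dpp4 (-3.94), Mpo (-3.70), Tnip3 (-3.61), the actin bundler Fscn1 (-3.60), Chil3 (-3.56), Elane (-3.53), the transcription factor Spib (-3.49) and Flt3 (-3.46) fell the most. In total 1281 genes passed, 487 rising and 794 falling, with 1280 free of overlap between arrays, a state that held for 44.2% of all genes against 10% by chance. Without day 10 replicate 3 the number was 1467.

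Eosinophil surface receptors rose in 9 of 15 between the days (camera adjusted p = 2.57e-09, and 0.0178 with an estimated correlation). The granule list had 0 of 7 genes past the test but was called by camera (adjusted p = 0.0342; adjusted p = 0.268 with an estimated correlation), a call lost without day 4 replicate 2 (0.0619) or 3 (0.0501), in a range from 0.0232 to 0.268 over all alternatives. Cebpe (1.42), Trib1 (1.21) and Id2 (1.03) rose with Gata1, and Irf8 (-2.96) and Cebpa (-1.05) fell (camera adjusted p = 0.0105; adjusted p = 0.204 with an estimated correlation), while Gata2 (0.68), Spi1 (0.32) and Xbp1 (-0.39) did not pass. Cebpa and Id2 lay near the 2-fold limit, at -0.95 after quantile normalization for Cebpa and, for Id2, 0.97 without day 4 replicate 1 and 0.99 without day 10 replicate 1. Of progenitor genes Flt3, Kit (-2.28), Sox4 (-1.41) and Cd34 (-1.34) fell and Gfi1b rose by 1.90 (camera adjusted p = 0.015; adjusted p = 0.093 with an estimated correlation). Of the IL-5 and STAT5 targets Cish (2.75), Socs2 (1.56), Pim2 (1.36), Socs1 (1.18) and Bcl2l1 (1.05) rose, and Ccnd1 (-1.94), Ccnd2 (-1.72) and Egr1 (-1.02) fell (camera adjusted p = 0.0107, and adjusted p = 0.226 with an estimated correlation). The other probe set of Socs2 gave 1.02. Bcl2l1 missed the 2-fold limit without day 4 replicate 3 (0.98) or day 10 replicate 3, and Egr1 without day 4 replicate 3 (-0.99), day 10 replicate 1 (-0.97) or 2 (-0.99).

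Dendritic cell markers fell in 13 of 18 after day 4, with Ccl22 at -3.44, Siglech at -3.28, the class II regulator Ciita at -2.72, Bst2 at -1.79 and Itgax at -1.67 besides Ccr7 and Flt3 (camera adjusted p = 5.04e-14, and 0.0205 with an estimated correlation). Antigen presentation genes fell in 9 of 17, with H2-Ab1 at -2.86, H2-Aa at -2.64, Cd74 at -2.61 and Ctss at -1.18 (camera adjusted p = 3.84e-10, and 0.0447 with an estimated correlation). Interferon-stimulated genes fell in 12 of 26, led by Mx1 (-2.34), Mx2 (-2.07) and Cxcl10 (-2.02), with camera adjusted p = 1.33e-10 and adjusted p = 0.216 with an estimated correlation. Later neutrophil genes fell in 12 of 20, such as Camp (-2.20) and Ltf (-1.97), and Retnlg (1.87) and Ly6g (1.14) rose (camera adjusted p = 0.000229; adjusted p = 0.303 with an estimated correlation). Primary granule genes fell in 7 of 10, Prtn3 by 3.34 (camera adjusted p = 1.42e-06; adjusted p = 0.12 with an estimated correlation). Monocyte markers fell in 7 of 21, with Ccr2 (-2.36), Cd14 (-2.28), Cx3cr1 (-1.81) and F13a1 (-1.62), and Adgre1 rose by 1.32 (camera adjusted p = 0.000279; adjusted p = 0.406 with an estimated correlation). Leaving out day 10 replicate 3, 11 monocyte markers fell. B cell markers fell in 5 of 14, Il7r (-2.24), Cd79b (-2.16), Blnk (-1.89), Ms4a1 (-1.60) and Cd79a (-1.40), and mast cell markers in 3 of 15, Kit, Cpa3 (-1.96) and Cma1 (-1.58). Both calls held (camera adjusted p = 0.000213 and 0.000116), with adjusted p of 0.0463 and 0.0462 with an estimated correlation.

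Immediate early genes fell in 7 of 25, with Fos (-2.06), Atf3 (-1.82) and Nr4a1 (-1.56), and Gadd45a rose by 2.13 (camera adjusted p = 0.00337; adjusted p = 0.209 with an estimated correlation). Cytokine receptors fell in 9 of 33, with the gp130 gene Il6st at -3.20 (camera adjusted p = 0.00048; adjusted p = 0.277 with an estimated correlation). Cytokines were not shifted as a list (camera adjusted p = 0.728), with 14 of 52 falling, Il12b by 3.37 and Ccl5 by 2.98, and 6 rising, Csf1 by 3.12 and Il4 by 1.49, where 7 rose when adjusted over the list alone. Ribosome biogenesis had a median change of -0.72 (camera adjusted p = 1.72e-12; adjusted p = 0.0505 with an estimated correlation). Tsr1 (-1.09), Nop16 (-1.07), Rrs1 (-1.02) and Dkc1 were its 4 members past the test, against 0 after quantile normalization, 2 without day 10 replicate 1 and 8 without day 10 replicate 3. Without day 10 replicate 1, Nop16 stood at -0.99 and Rrs1 at -0.91, and Rrs1 was at -0.92 without day 4 replicate 1. Dkc1 missed the limit without day 4 replicate 2 or 3 (-0.99) or day 10 replicate 2 (-0.98). DNA replication genes fell in 6 of 33, Prim1 (-1.18), Cdt1 (-1.18), Gins1 and Mcm2 (-1.09) leading, against 4 without Gins1 after quantile normalization (camera adjusted p = 8.1e-15, and 0.0368 with an estimated correlation). Mitosis genes had a median of -0.48 and 0 of 29 past the test, Bub1 at -0.88 and Kif23 at -0.83 (camera adjusted p = 6.59e-10; adjusted p = 0.0862 with an estimated correlation). Oxidative phosphorylation had a median of -0.34 and 0 of 35, Cycs at -0.81 and Ndufs3 at -0.72 (camera adjusted p = 3.14e-05; adjusted p = 0.243 with an estimated correlation).

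Of the glycolysis list, Slc16a3 (2.05), Slc2a3 (1.76), Slc2a1 (1.54) and Hk2 (1.19) rose from day 4 to day 10, while Hk3 (-1.48) and Pfkfb3 (-1.12) fell (camera adjusted p = 0.00166; adjusted p = 0.298 with an estimated correlation). Cholesterol synthesis shifted down, Insig1 (-1.39) and Idi1 (-1.02) falling (camera adjusted p = 6.85e-06; adjusted p = 0.0854 with an estimated correlation). Idi1 stood at -0.99 without day 4 replicate 1, -0.98 without day 4 replicate 3, -0.91 without day 10 replicate 1 and -0.97 with its probe sets averaged, and missed the limit after quantile normalization, leaving 1 fall each time an array was left out. Eicosanoid genes moved both ways without a shift of the list (camera adjusted p = 0.822), 7 of 24 rising, Alox15 by 2.79 and Alox5 by 1.97, and Cysltr1 (-1.93), Ptgs2 (-1.79), Pparg (-1.60) and Hpgds (-1.48) falling. Lysosome genes were not shifted (camera adjusted p = 0.0778, and 0.0137 without day 10 replicate 3, in a range from 0.0137 to 0.57), with Ctsz (-1.41) and Ctss down and Neu1 up. Without day 10 replicate 3, 4 lysosome genes fell, and without day 4 replicate 1, 2 rose. Neu1 lay at the 2-fold limit, at 0.92 without day 4 replicate 3, 0.98 without day 10 replicate 2 and 0.98 after subtraction of array medians. Adhesion genes (camera adjusted p = 0.661) rose in 3 of 22, Itga2 (1.52), Itgb7 (1.29) and Itga2b, and fell in 6, Itga1 by 1.95 and Thbs1 by 1.35. Basophil (0.751), erythroid (0.966), megakaryocyte (0.847), T and NK cell (0.636), stromal (0.394), apoptosis (0.653), unfolded protein response (0.432) and histone (0.248) lists were not shifted either, by camera adjusted p. Within them F2r (2.41), Cyp11a1 (1.64), Cd3d (1.39) and Itga2b rose, Kdr (-2.35), Fcer1a (-1.55), Klrd1 (-1.51), Cd69 (-1.46), Pmaip1 (-1.07) and Tnfsf10 (-1.02) fell, and Herpud1 (0.56), Trib3 (0.48), H1f2 (0.89) and H2bc21 (-0.63) did not pass. Tnfsf10 stood at -0.88 without day 4 replicate 2 and at -0.76 without day 10 replicate 2, and Pmaip1 at -0.98 after quantile normalization. Of 33 lists 21 were shifted, 5 up and 16 down, and 6 calls held with an estimated correlation. Fry also called the eicosanoid (adjusted p = 0.0104) and unfolded protein response lists (adjusted p = 0.0332), which camera did not.

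**Figure D3:**
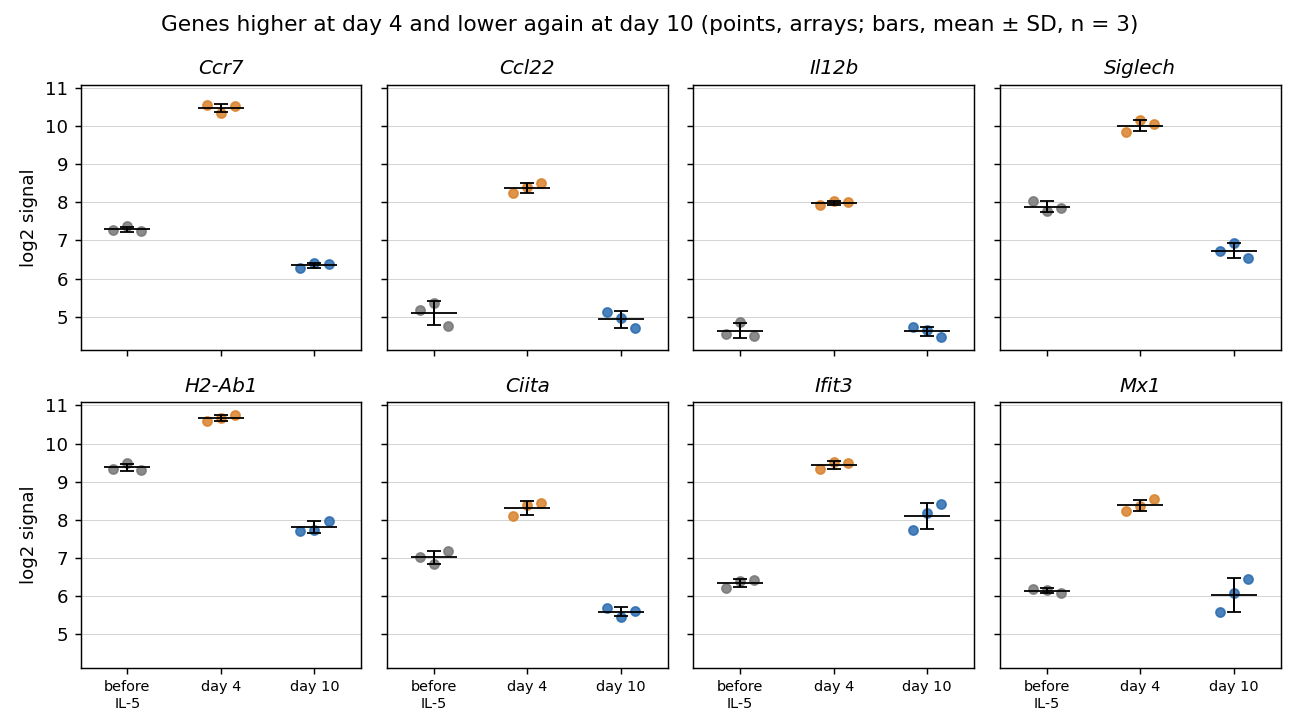
Log2 signal of 8 genes in each of the 9 arrays (points), with the mean and SD of 3 arrays (bars). All 8 rose at day 4 and fell from day 4 to day 10, Ccr7 from 10.47 to 6.35 and Siglech from 10.01 to 6.74, and Ifit3 at 8.11 stayed above its level before IL-5.

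Read over the 3 times, 306 genes rose and 402 fell at both days, 361 rose late and 322 fell late, and 234 rose transiently while 3 fell transiently. Transient rises were led by Ccr7, Fscn1, Ccl22, the lipase Lpl (-3.39 from day 4 to day 10), Il12b (-3.37) and the chemokine receptor Ccr9 (-3.31). The 3 transient falls were Cdh17 (1.95 back up), Gfi1b (1.90) and Gimap9 (1.07), and Gimap9 came back by 0.96 without day 4 replicate 3. Late rises were led by Cyp4f18, Tmem71, Aqp9, Slc16a9, Enah and Cd3g, and late falls by Ctsg, Dpp4, Mpo, Elane, Spib and Flt3. In 100 simulations of unchanged groups sharing the arrays, 0 genes on average entered each of these classes. The day 4 and day 10 changes against the cells before IL-5 correlated across genes with Pearson's r of 0.677, where unchanged groups sharing those 3 arrays gave 0.499, and genes are not independent replicates. The covariance was 0.253 against a simulated 0.00855. Independent lists of these sizes would share 33.0 rises and 39.5 falls. The 3 arrays before IL-5 are too few to be split into parts of 2 or more, so part of the excess over independent lists may come from sharing them.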

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

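Of the tests below, those of a lower share of eosinophil-lineage cells and of more dendritic cells were chosen only after the result was seen, as were quantile normalization and subtraction of array medians for the time course classes.

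A set of 27 genes stood higher at day 4 and lower at day 10 than before IL-5, with both changes past the test. The day 10 against day 4 test called each of them, which follows from this choice and adds no support. The class II genes H2-Ab1 (1.30 at day 4 and -1.56 at day 10), H2-Ea (1.55 and -1.56), H2-Aa (1.18 and -1.46) and H2-Eb1 (1.11 and -1.24) were among them. So were the plasmacytoid dendritic cell genes Siglech (2.13 and -1.15) and Tcf4 (1.06 and -1.72), the kynureninase gene Kynu (1.80 and -1.49), the lectins Clec10a (1.30 and -1.30) and Mgl2 (1.53 and -1.44), and Ly86 (1.25 and -1.99). Their changes from day 4 to day 10 ran from -3.61 for Tnip3 (adjusted p = 5.98e-09) to -2.24 for Il7r (adjusted p = 8.25e-06). With an array left out the set held 26 to 34 genes. Il7r missed the 2-fold limit at day 4 without replicate 1 (0.99) or replicate 3 (0.97) before IL-5, and Chil3 missed it at day 10 without day 10 replicate 1 (-0.68) or replicate 1 before IL-5 (-0.94).

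The opposite course was taken by 1 gene, Nqo1, which encodes a quinone reductase, singled out because its values went against the rest. It fell from 8.14 ± 0.319 before IL-5 to 6.95 ± 0.197 at day 4 and reached 9.83 ± 0.049 (SD, n = 3) at day 10. The call of its day 10 against day 4 change of 2.88 (adjusted p = 2.03e-08) again follows from the choice.

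Apart from these, 234 genes rose at day 4 and fell from day 4 to day 10 without passing against the cells before IL-5 at day 10. Array scaling as the whole cause is argued against for the 234 by the 225 such genes after quantile normalization and the 246 after subtraction of array medians. A lower share of eosinophil-lineage cells at day 4 was predicted to raise the markers of every other cell type alike. The B cell markers instead had a median change of -1.49 at day 4, with quartiles of -2.49 and -0.711. They stood lower still at day 10 against the cells before IL-5, with a median of -1.99. Their own decline in the culture could hide such an effect, so this test cannot decide. Eosinophil surface receptors rose in 10 of 15 at day 4 with 0 falling. Of 7 granule list genes 4 rose and 1 fell. These values argue against a share lower at day 4 than before IL-5. A share lower at day 4 than at day 10 stays open for the fall between the days. More dendritic cells in the day 4 cultures may contribute and stay open, since 10 of 18 dendritic cell markers (55.6%) rose at day 4, among them the abundant Ccr7 and Bst2 at levels of 10.47 and 10.13, while 4 of the 13 that fell back by day 10 had not risen at day 4. IL-5 itself, any change in the earlier growth factors and time in culture remain open, untested in this design. No sort by cell type is given in the sources used here.

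Probe sets naming several genes, left out of the comparisons, held 162 of 1621 that passed at day 10 against the cells before IL-5, with 32 rising and 130 falling. Probe sets absent from the probe table used here held 1220 of 12147 that passed in the same comparison, with 764 rising and 456 falling.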

How the results depend on the processing

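Quantile normalization of the list shifts and of the time course classes, and subtraction of array medians for these classes, were the tests chosen only after the result was seen. Every probe set of the table gave 1663 changed at day 4 and 4496 at day 10, where more features were tested. With no fold threshold 6279, 8440 and 6364 genes passed at day 4, at day 10 and between the days, and the classes held 1421 sustained rises, 3346 sustained falls, 1023 late rises, 1123 late falls, 518 transient rises, 157 transient falls, 240 genes up then down and 56 down then up. Of the genes classed as reported, 170 of 361 late rises, 177 of 322 late falls, 152 of 234 transient rises and 2 of 3 transient falls kept their class. At least 4-fold left 184, 493 and 237 genes, and these counts follow from the thresholds. With an estimated correlation in camera 10, 6 and 6 lists were called, and the cause was not tested. Transient falls numbered 2 to 5 with an array left out, 5 of them without day 4 replicate 2. Camera on ranks lost the calls of eosinophil granule genes (0.057), lineage factors (0.178), basophil markers (0.137) and IL-5 targets (0.0831) at day 4, of basophil markers (0.129) and adhesion genes (0.0932) at day 10, and of progenitor genes (0.0576) between the days. Leaving out genes below the lower quartile lost the unfolded protein response at day 4 (0.0892) and the granule genes between the days (0.0574), and the cause was not tested.

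With the title numbers as a replicate block 1103, 2842 and 1282 genes passed, 1102, 2839 and 1281 of them shared with the fit without it, 27, 25 and 21 lists were called, and no named gene's call changed. The numbers did not pair the arrays, since the 9 same-numbered pairs had correlations of deviations from -0.119 to 0.077, 0 of them over 0.1, and 0 of 9 arrays lay closest to their own number. The numbers in the sample descriptions gave 3 pairs from -0.061 to 0.063, and as a random replicate block 1101, 2840 and 1279 genes, with the calls of Bid at day 4 and Neu1 between the days lost at the 2-fold limit.

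Leaving out each array in turn gave 1076 to 1157, 2739 to 3004 and 1191 to 1467 genes, 25 to 28, 25 to 26 and 20 to 22 lists, and a correlation of the day 4 and day 10 changes from 0.648 to 0.691. Of 3402 results of named genes without 1 array, 3369 kept their call, 30 lost it and 3 gained it, and of 6023 under the other settings 5813 kept it, 176 lost it and 34 gained it. For lists, 881 of 891 calls were kept without 1 array, with 6 lost and 4 gained, and 534 of 594 otherwise, with 60 lost. Under the alternatives run, 0 named genes and 0 lists reversed. Quantile normalization lost 11 of 378 named gene results, the farthest from the 2-fold limit being Dkc1 between the days at -0.89, and put the share of falls at 33.2%, 57.8% and 57.1%, against 38.1%, 66.0% and 62.0% as deposited. It also gave 9 instead of 6 rising immediate early genes at day 10, and subtraction of array medians 6 instead of 4 falling ribosome biogenesis genes between the days, while several lists with 0 to 3 calls in a direction gained or lost 1. A test against a 1.5-fold null (limma's treat) lost Acta2 and Col1a2 at day 10 and F13a1, Il4, Rrs1 and Tnfsf10 between the days. Robust averaging compresses changes close to background, which limits what can be said of the size of changes in dim genes.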

Other observations

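The test of T or NK cells was chosen only after the result was seen, and so were the genes described here.

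By day 10 a further set of genes stood far above its level before IL-5. The metalloproteinases Adam8 (4.41), Mmp27 (4.37) and Mmp25 (3.98) rose together with Timp2 (3.85), a metalloproteinase inhibitor. Adam8 and Mmp25 had already risen by day 4, by 2.92 and 2.93, and Mmp27 rose by 3.66 from day 4 to day 10. The semaphorin Sema7a (4.46), coagulation factor F5 (4.01), the ATP-gated channel P2rx1 (3.89), the signalling genes Camk1 (4.43) and Rasgrp4 (4.09), the repressor Bhlhe40 (4.06), the monoglyceride lipase Mgll (3.66) and the arginase Arg2 (3.19) rose as well. Among the falls were the transcriptional repressors Gfi1 (-2.36) and Bcl11a (-2.92), Ms4a3 (-2.87) and the serpin Serpinb1a (-2.73).

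Other genes that rose at day 4 were the lipid transfer protein gene Pltp by 3.26, Apoe by 2.38, the cholesterol exporter Abca1 by 2.44, the receptor kinase Axl by 2.99 and the protease gene Lgmn by 2.71, with Ms4a7 (3.89), Siglec1 (3.15) and Tlr13 (2.94). From day 4 to day 10 Axl fell by 1.99 and Siglec1 by 1.07, whereas Pltp (-0.93), Ms4a7 (-0.77), Lgmn (-0.66), Apoe (-0.45), Abca1 (0.04) and Tlr13 (-0.05) did not pass. Siglec1 stood at -0.99 without day 4 replicate 2 and at -0.97 after quantile normalization. Without day 10 replicate 3, Pltp (-1.15), Lgmn (-1.07) and Ms4a7 (-1.05) passed, as Pltp (-1.01) did with array weights. Both Kmo (-3.42) and Kynu (-3.29), which encode enzymes of tryptophan breakdown, fell between the days, as did the dendritic cell receptor Clec9a (-2.52) and the signal transducer Stat4 (-2.62). The retinoid receptor gene Rxra (2.29) and Ikzf3 (2.72) rose. The other results given for these further genes were on the same side of the test in 22 of 22 alternatives, leaving out each array among them and with other fold thresholds and the test of every probe set not counted.

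Of the T and NK cell markers Cd3g and Cd3d stood apart, going from 4.10 ± 0.478 and 5.07 ± 0.382 at day 4 to 7.84 ± 0.08 and 6.46 ± 0.114 (SD, n = 3) at day 10, higher in 3 of 3 arrays. T or NK cells in the day 10 cultures are argued against, since the other markers had a median change of 0.0135 with quartiles of -0.295 and 0.175, and Cd3e, at 5.53 on day 10, changed by 0.24 with a 95% interval from -0.0827 to 0.571, below the 1.39 of Cd3d. Transcription running in from neighbouring genes is argued against by the median change of 0.106 among the 4 measured genes on each side of Cd3g, Cd3d and Cd3e in GRCm38.p6 order, with quartiles of -0.117 and 0.18. The only neighbour past the test was Jaml, which fell by 1.25. A response to IL-5, to any change in the earlier growth factors or to time in culture stays open, untested.

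More genes fell than rose at day 10 against the cells before IL-5, 66.0% of those past the test. The share depends on the probe sets tested. Over every probe set of the array 58.7% fell, and among those absent from the probe table used here 764 rose and 456 fell. Compression of rises in dim genes is argued against, since 65.7% fell among the brighter part of the genes. Array scaling may account for part of it and stays open, as 57.8% fell after quantile normalization and 66.2% after subtraction of array medians. IL-5, any change in the earlier growth factors and time in culture stay open too, untested.

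The 6 arrays of a comparison can be split into equal groups in 10 ways, too few for a share under 0.05. In each comparison 1 split, the real one, gave the most genes, 1102 at day 4, 2839 at day 10 and 1281 between the days, and the highest of the other splits gave 0. The other splits mix both times in each group, so genes that differ between the times gain spread there. Their 0 therefore does not show whether the arrays of a group are independent.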
